A study of Arabidopsis thaliana with 27 samples.

How the data were processed

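RNA from whole rosettes of 27 Arabidopsis samples was hybridised to ATH1-type arrays that hold 22810 probe sets. Per the labels' protocols, plants grew in soil under 16 h light and 8 h dark at 75 µmol quanta of light per square metre and second, 22 °C by day and 18 °C by night. Total RNA from 2 rosettes per sample was taken with TRIzol and purified on RNeasy columns, and biotinylated cRNA was made with the GeneChip 3' IVT Express kit. Groups were taken from the sample labels: 3 genotypes in 3 conditions with 3 biological replicates each.

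The authors deposited log2 signals, 1 per probe set and array. Per the submitters' processing notes, RMA or GCRMA from the affy package family in R 2.15.0 was used; both names stand there, so which of these made the values was not settled. The values run from 1.61 to 13.59 with none missing, and 21.2% of them lie between 2 and 3, near the background. Signals near the background limit what can be seen for weakly expressed genes. All value columns were matched to a sample by label, with 0 left unmatched.

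After removal of 64 control probe sets 22746 were tested. The reference table paired 13513 of these with a single gene, 503 with several and 8730 with none. Of the single-gene probe sets 13436 were matched to the reference annotation and 77 were not, which gave 13356 distinct genes. Only single-gene probe sets are named as genes, and probe sets with no paired gene are counted in every total. Catalase and glycolate oxidase genes were not among the paired ones, so their levels are not analysed here.

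Differences were fitted with limma 3.58.1 in R 4.3.3 on all 27 arrays with 1 mean per group, and empirical Bayes variances with default settings. There were 14 contrasts, 11 between pairs of groups and 3 differences between transfer responses. P-values were adjusted by Benjamini-Hochberg within each contrast over all probe sets tested, and an adjusted p under 0.05 counted as a call. Tests were two-sided. Because the variance is pooled over all groups, a comparison with 1 array left out, which leaves 2 arrays in that group, assumes that these vary like the other groups.

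Gene lists were tested with camera in limma at its preset correlation of 0.01 and again with an estimated correlation, on 1 probe set per gene, the 13356 genes as background. Of 29 lists fixed with 571 distinct loci, 13 had at least 3 measured members and were tested in 14 contrasts, and the 182 p-values were adjusted together. With the preset correlation 50 tests passed, and 6 of these passed with the estimated one. The latter were the detoxification list in cat2 and in GO5 against WT at ambient CO2, in the GO5 transfer response and in GO5 minus WT, and the flavonoid list in the WT and cat2 transfer responses. Most lists had few measured members because 8730 probe sets have no gene name here, and marker lists of other organs and cell types had 0 to 2 measured members and were not tested. Counts adjusted over the list alone use the members' p-values only.

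Genes were named by a rule. In each contrast it took the 8 largest increases and 8 largest decreases among called single-gene probe sets whose arrays did not overlap between the groups, or, for differences of responses, with the same sign in every replicate, taken over arrays with the same replicate number. It added up to 4 called members of each list that passed. The lists, contrasts, thresholds, named-gene rule and alternatives were fixed before the data were examined, except where the text says otherwise.

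The 3' and 5' probe sets of the GAPDH and actin controls gave the RNA quality differences, compared by exact two-sided permutation tests. With 3 against 3 arrays these cannot give a p below 0.1. Actin 3'/5' differences were 0.04 for cat2 against WT at ambient CO2 (exact p = 0.9) and 0.20 for GO5 (exact p = 0.7). They were -0.28 for cat2 against WT at high CO2 and 0.31 for WT at 8 h against 0 h (exact p = 0.1 each, the smallest possible), in the same direction as GAPDH. In the other 7 pairwise comparisons the exact p for actin was 0.2 or more. Comparisons that share the WT arrays were set against 100 simulated draws with no effects and the same sharing.

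Alternatives were quantile normalization, median centring, array weights, variances with trend and robust settings, dim probe sets left out (below percentile 40 of mean signal), only the arrays of the groups compared, replicate number as a block and each array left out in turn. A fit without the 2 arrays that stood apart from their groups and a fit with the GAPDH difference as a covariate were added after seeing the data. The array weights did not converge and gave 1 WT ambient array a weight of 19.6. The fit was tested on simulated data: of 100 planted changes of 2 log2 units it recovered 97 in the cat2 against WT design and of 100 changes of 1 log2 unit 85, with 4 unchanged probe sets called. In the cat2 minus WT transfer design it recovered 93 of 100 changes of 2 log2 units and 64 of 100 changes of 1, again with 4 unchanged called. With nothing planted, tried only in the design of cat2 against WT at 0 h, it called 0. The simulated noise was normal, independent between arrays and probe sets, and equal in spread in every group. It lacks the structure of the real arrays, so these figures do not give the error rates on them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared tables and drew the plots.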

Results

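Transcript levels were measured in whole Arabidopsis rosettes on 27 ATH1-type arrays. The plants were wild type Col-0 (WT), the catalase-deficient mutant cat2-2 (cat2), which removes less of the H2O2 that photorespiration forms in peroxisomes, and a line with glycolate oxidase in the chloroplasts (GO5), which forms H2O2 there. All grew at 3000 ppm CO2 and were harvested at 3 weeks, either at 0 h, 8 h after a move to 380 ppm (ambient), or after the same 8 h at 3000 ppm (high CO2). Each of the 9 groups held 3 biological replicates of 2 rosettes. Values are log2 signals, and a difference is given as log2 ± SE of the fitted difference (n = 3 arrays per group). The number of arrays limits the precision of every value. For a gene named with a pairwise difference, the values of the groups did not overlap (3 against 3 arrays) unless said otherwise.

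Array medians lay between 5.28 and 5.52, and correlations within groups between 0.963 and 0.995. The first principal component took 44.8% of the variance and the second 16.7%. The WT ambient arrays had the largest median SD over probe sets, 0.237, against 0.122 to 0.172 in the other 8 groups. The difference between the 3' and 5' GAPDH control probe sets, a sign of RNA quality, was 2.12 ± 0.61 log2 (SD, n = 3) in WT at ambient and 2.09 ± 0.31 in WT at high CO2, against 1.53 ± 0.08 in WT at 0 h, 1.605 ± 0.11 in cat2 at ambient and 1.49 ± 0.15 in GO5 at ambient. No probe set paired with a single gene here stood for a catalase or a glycolate oxidase gene, so the genotypes were not checked on the engineered genes themselves.

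Which transcripts differed in cat2 after 8 h at ambient CO2, where photorespiration feeds peroxisomal H2O2, was asked first. GSTU25, a tau-class glutathione transferase, was 32.5-fold higher in cat2 than in WT (5.02 ± 0.49, n = 3, adjusted p = 3.9e-06). The small heat shock proteins AT5G51440 of mitochondria (3.87 ± 0.73) and AT2G29500 and AT1G53540 of the cytosol (3.39 ± 0.54 and 2.78 ± 0.43) rose with the co-chaperone Hop3 (2.42 ± 0.54) and the FKBP-type isomerase AT5G48570 (2.28 ± 0.50). AT3G55920 (4.003 ± 0.09) and AT4G01870 (3.33 ± 0.57) were also higher. Among single-gene probe sets decreases were smaller: AT3G61920 changed by -0.95 ± 0.21, the leucine-rich repeat gene AT3G17640 by -0.85 ± 0.18, AT2G20480 by -0.84 ± 0.19, AT5G44010 by -0.78 ± 0.16, AT3G59650 by -0.66 ± 0.15, AT3G42725 by -0.64 ± 0.14, the J-domain gene AT2G33735 by -0.64 ± 0.14 and the carboxypeptidase-like scpl50 by -0.63 ± 0.14. A probe set not paired with a gene here changed by -3.94 ± 0.43.

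Among the lists, 3 of 7 measured glutathione transferase and detoxification genes rose in cat2 and none fell (5 adjusted over the list alone). The detoxification list median was 1.02 log2 (camera adjusted p = 2.38e-09, and adjusted p = 0.0372 with an estimated correlation). Besides GSTU25, its members GSTU22 (1.33 ± 0.25) and the glycosyltransferase UGT73B1 (1.02 ± 0.18) rose. Of the 7 heat shock genes, 4 rose and none fell (4 adjusted over the list alone). The heat shock list median was 2.28 log2 (camera adjusted p = 8.18e-06, and adjusted p = 0.105 with an estimated correlation). The oxidative stress markers ranked above other genes with 0 of 6 members past the limma threshold (2 at an unadjusted p under 0.05, 1 adjusted over the list alone). The marker list median was 0.78 log2 (camera adjusted p = 0.00152, and adjusted p = 0.27 with an estimated correlation). The endoplasmic reticulum folding genes also ranked above other genes with 0 of 4 past it (1 at an unadjusted p under 0.05, 1 adjusted over the list alone). The folding list median was 0.31 log2 (camera adjusted p = 0.0224, and adjusted p = 0.345 with an estimated correlation).

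At an unadjusted p under 0.05, 1227 probe sets were higher and 1994 lower in cat2. The adjusted threshold was passed by 160 in all, 117 higher and 43 lower in cat2 (118 and 23 after median centring), 61 of them by 2-fold or more. The values of the 3 cat2 and 3 WT arrays did not overlap for 156 of these, and for 10.8% of all probe sets, where chance gives 10%. The GAPDH 3'/5' measure was lower in cat2 than in WT (difference -0.52 log2, exact two-sided permutation p = 0.1, the smallest possible with 3 against 3). With this measure as a covariate 146 passed, 87 of them among the 160. The count was 433 without the 2 arrays taken to stand apart from their groups, WT ambient replicate 1 and cat2 ambient replicate 3. Their mean correlations with their own groups were 0.969 and 0.982. WT ambient replicates 2 and 3, which were kept, also lay below 0.982 (0.974 and 0.980). Array weights gave 6532 (2938 and 3594, a turned majority), a fit that rests largely on 1 WT array. The 6 compared arrays alone gave 7. Leaving out WT ambient replicate 1, 2 or 3 gave 100, 1072 and 388 calls and cat2 ambient replicate 1, 2 or 3 gave 61, 62 and 639, and of the 18 genes named here 6 passed whichever array was left out (10, 2 and 1 were lost without those WT arrays and 11, 11 and 1 without those cat2 arrays).

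**Figure D1:**
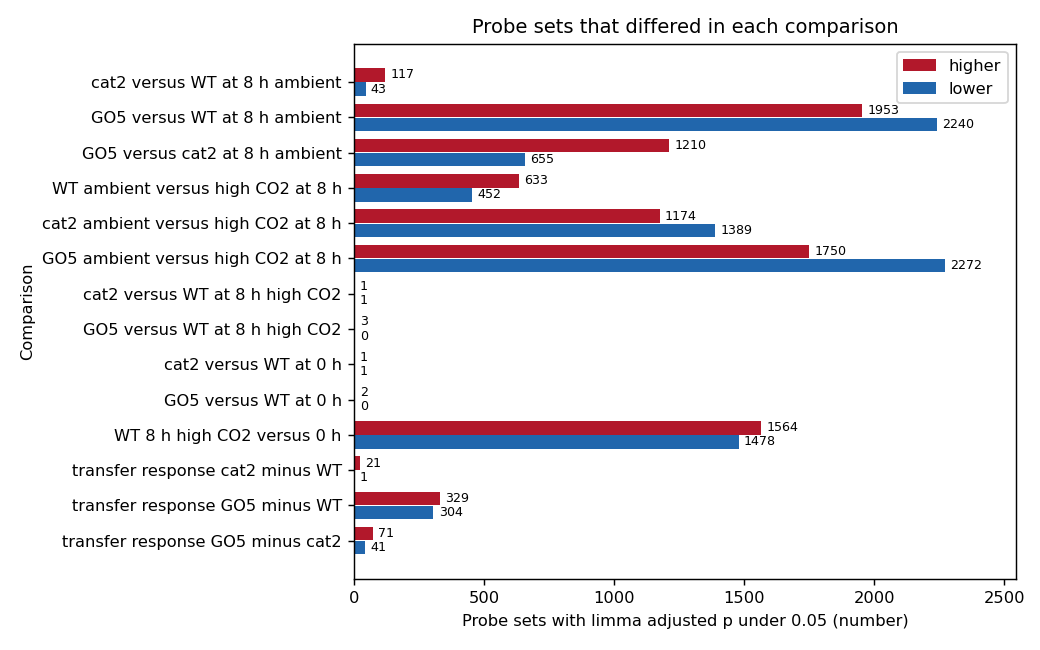
Number of probe sets past an adjusted p of 0.05 in each comparison, with 1 bar for those higher and 1 for those lower, from limma on 22746 probe sets and 27 arrays. In GO5 against WT at ambient CO2 1953 were higher and 2240 lower, and in cat2 against WT 117 and 43.

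The same question for H2O2 of plastid origin compared GO5 with WT at ambient CO2. The MATE-type efflux carrier AT2G04050 was 124-fold higher in GO5 (6.95 ± 0.58, n = 3, adjusted p = 8.17e-08), and its relative AT2G04070 rose by 4.82 ± 0.35. AT2G41730 (5.75 ± 0.48), the mitochondrial small heat shock protein AT5G51440 (4.69 ± 0.73), the AAA-type ATPase AT2G18190 (4.25 ± 0.41), the GNAT acetyltransferase AT2G32020 (4.24 ± 0.32), AT2G20720 (4.21 ± 0.35) and the berberine bridge-like oxidase AT1G26380 (3.97 ± 0.63) followed. The decreases were TBL26 at -1.64 ± 0.38, AT1G52770 at -1.62 ± 0.55, the bHLH gene AT5G50915 at -1.596 ± 0.26, AT3G14395 at -1.43 ± 0.37, AT3G48490 at -1.41 ± 0.27, the coumarate ligase-like 4CL8 at -1.35 ± 0.31, AT1G52720 at -1.32 ± 0.29 and the GDSL lipase gene AT5G45960 at -1.30 ± 0.26.

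Of the 6 oxidative stress markers 5 rose in GO5 (5 adjusted over the list alone), among them the AAA-type ATPase AT3G28580 (3.96 ± 0.40), AT2G21640 (3.45 ± 0.40), AT1G10585 (3.24 ± 0.53) and AT1G19020 (3.00 ± 0.63). The median marker difference was 3.12 log2 (camera adjusted p = 1.78e-07, and adjusted p = 0.074 with an estimated correlation). The detoxification list had 5 of 7 members higher (6 adjusted over the list alone). The median detoxification difference was 2.98 log2 (camera adjusted p = 2.38e-09, and adjusted p = 0.0372 with an estimated correlation). GSTU25 rose by 3.32 ± 0.49, UGT73B4 by 3.03 ± 0.30 and UGT73B5 by 2.98 ± 0.35. Early-response genes rose in 3 of 5 cases (4 adjusted over the list alone): the zinc finger gene STZ (2.17 ± 0.68), WRKY6 (1.95 ± 0.50) and the calmodulin-like CML37 (1.45 ± 0.50). The early-response list median was 1.55 log2 (camera adjusted p = 0.0117, and adjusted p = 0.45 with an estimated correlation). Photorespiration genes fell in 3 of 8 cases and rose in none (5 lower adjusted over the list alone), namely the hydroxypyruvate reductase AT1G79870 (-0.60 ± 0.14), the plastid glycolate and glycerate carrier LrgB (-0.45 ± 0.14) and the glycerate kinase AT1G80380 (-0.40 ± 0.10). The photorespiration list median was -0.35 log2 (camera adjusted p = 0.045, and adjusted p = 0.465 with an estimated correlation). For the heat shock list the median was -0.20 and the mean 0.41, opposite in sign, and the test did not pass (adjusted p = 0.99, 0.997 with an estimated correlation).

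The threshold was passed by 4193 probe sets, 1953 higher and 2240 lower in GO5 (1564 and 3412 after median centring). By 2-fold or more, 698 were higher and 77 lower. No overlap between GO5 and WT arrays was seen for 3582 of the calls and for 25.2% of all probe sets, against 10% by chance. GAPDH 3'/5' was lower in GO5 (difference -0.63 log2, exact permutation p = 0.1, the smallest possible). With GAPDH 3'/5' as a covariate 4484 passed, 3228 of them among the 4193. Array weights, resting largely on 1 WT array, gave 6764 calls, and the 6 compared arrays alone gave 206 (187 higher and 19 lower, which turns the majority). Without GO5 ambient replicate 2 the count was 1926, and 21 of the 29 named genes passed whichever array was left out (1, 7 and 3 were lost without GO5 ambient replicates 1, 2 and 3, and 4, 3 and 1 without WT ambient replicates 1, 2 and 3).

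**Figure D2:**
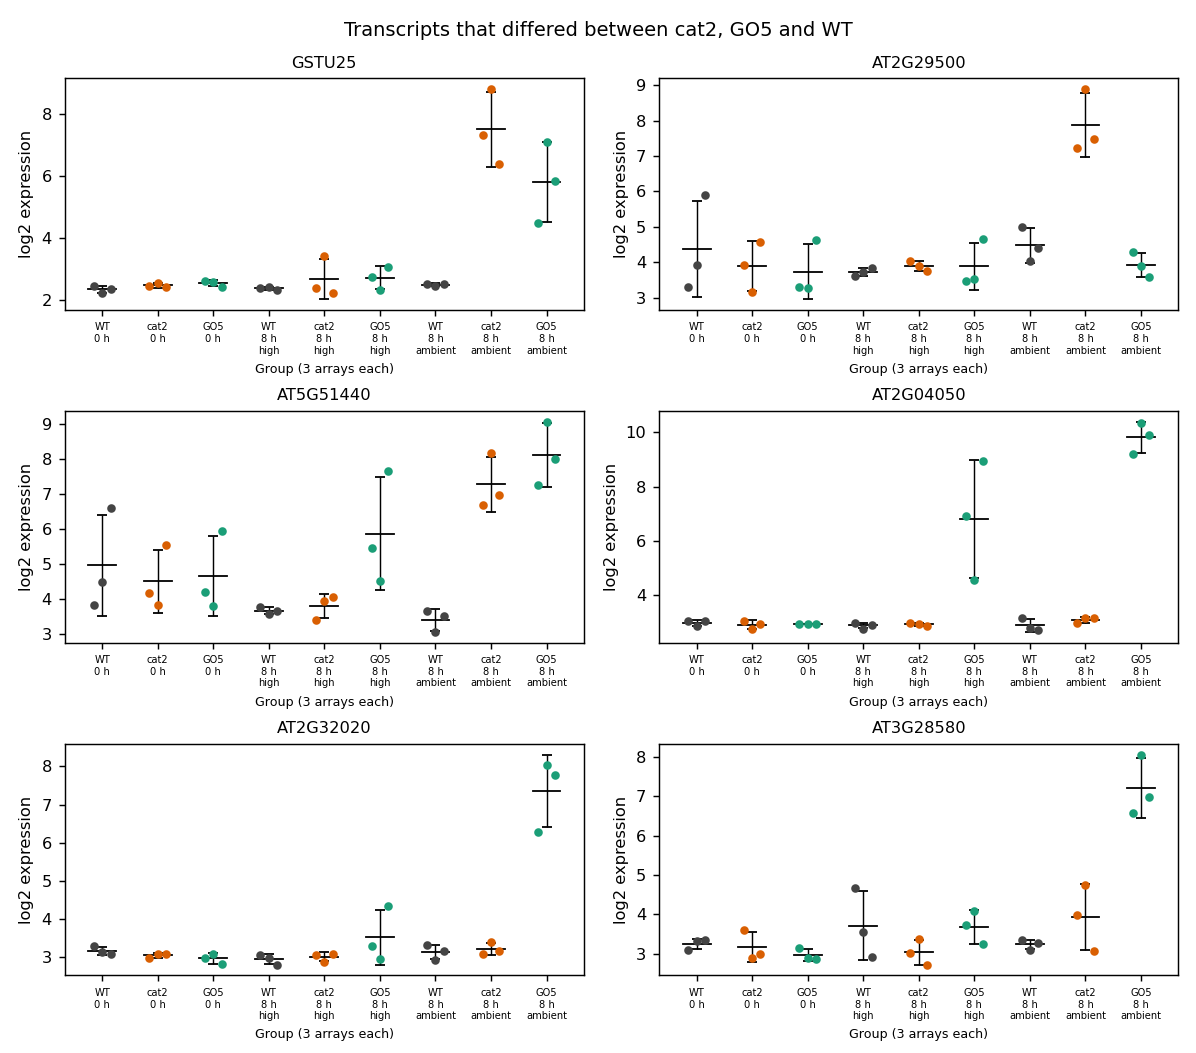
Log2 signal per array (points) with the mean and SD of 3 arrays in 9 groups for 6 genes. GSTU25 was 5.02 log2 higher in cat2 and 3.32 higher in GO5 than in WT at ambient CO2, and the difference of GO5 from cat2 in AT2G29500 was -3.95.

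GO5 and cat2 were then compared directly at ambient CO2. The lines differ in the site of H2O2 and also in the enzyme that was altered. H2O2 levels were not among the values here, so an effect of origin cannot be told apart from its amount or the line. AT2G04050 was higher in GO5 by 6.75 ± 0.58 (108-fold, n = 3, adjusted p = 1.64e-07), with AT2G04070 (4.48 ± 0.35), AT2G20720 (4.28 ± 0.35), AT2G18190 (4.24 ± 0.41), AT2G32020 (4.16 ± 0.32), AT2G41730 (3.92 ± 0.48), AT3G45730 (3.90 ± 0.47) and the alternative NAD(P)H dehydrogenase NDB4 (3.83 ± 0.36). Lower in GO5 than in cat2 were the small heat shock proteins AT2G29500 (-3.95 ± 0.54) and AT1G53540 (-3.02 ± 0.43), the J-domain gene AT1G71000 (-2.70 ± 0.50), Hop3 (-2.29 ± 0.54) and AT5G48570 (-2.24 ± 0.50). Also lower were AT5G16980 (-2.16 ± 0.24), AT3G22620 (-1.82 ± 0.44) and AT4G29520 (-1.62 ± 0.26).

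The heat shock list had 3 of 7 members lower in GO5 than in cat2 and none higher (3 adjusted over the list alone). The median heat shock difference was -0.50 log2 (camera adjusted p = 0.00156, and adjusted p = 0.27 with an estimated correlation). The oxidative stress markers had 3 of 6 higher (5 adjusted over the list alone): AT3G28580 (3.26 ± 0.40), AT2G21640 (2.48 ± 0.40) and AT1G19020 (2.31 ± 0.63). The marker list median was 1.97 log2 (camera adjusted p = 1.13e-05, and adjusted p = 0.12 with an estimated correlation). In the detoxification list 3 of 7 were higher and 1 lower (3 and 2 adjusted over the list alone, mean 1.23), with UGT73B4 at 2.13 ± 0.30, UGT73B5 at 1.76 ± 0.35 and GSTU25 at -1.70 ± 0.49, the arrays of the last 2 genes overlapping. The detoxification list median was 0.17 log2 (camera adjusted p = 0.0192, and adjusted p = 0.357 with an estimated correlation). Early-response genes ranked higher in GO5 than other genes with 0 of 5 past the limma threshold (3 at an unadjusted p under 0.05, 2 adjusted over the list alone). The median early-response difference was 1.07 log2 (camera adjusted p = 0.0302, and adjusted p = 0.524 with an estimated correlation).

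Past the threshold lay 1865 probe sets, 1210 higher and 655 lower in GO5 (905 and 979 after median centring, which turns the majority). Of these, 440 differed by 2-fold or more, and 1760 had no overlap (23.4% of all probe sets, 10% by chance). The 6 compared arrays alone gave 64 calls, leaving out cat2 ambient replicate 1 gave 997 and leaving out GO5 ambient replicate 2 gave 569. Of 22 named genes 17 passed whichever array was left out (1, 3 and 3 were lost without GO5 replicates 1, 2 and 3 and 3, 3 and 1 without cat2 replicates 1, 2 and 3).

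Among the probe sets past the threshold against WT at ambient CO2, 55 were higher in both lines, 35 lower in both and 2 opposite, where independent lists would share 10.1 and 4.24. Across probe sets the cat2 and GO5 differences had r = 0.574 and rho = 0.593. Both comparisons use the same 3 WT arrays, which alone produces a correlation: over 100 simulated draws with no effects the median r was 0.489 (-0.187 to 0.861) and the median rho 0.462. The covariance was 0.0863, against a simulated median of 0.0183 and highest of 0.0706. A wide spread of the shared WT arrays can raise it with no common response. Their median SD was 0.237, against 0.122 to 0.172 in the other groups. Deviations that cat2 and GO5 ambient arrays of the same replicate number share can raise it too (r = 0.295, 0.403 and 0.559). Each draw took deviations of random arrays from their group means, with random signs, and used 3 of them as the shared reference. It did not place the wider WT ambient spread in that reference or match replicate numbers. A covariance above the simulated range therefore does not decide whether the lines share a response. Probe sets are not independent replicates, and 3 WT arrays cannot be divided into groups of at least 2.

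**Figure D3:**
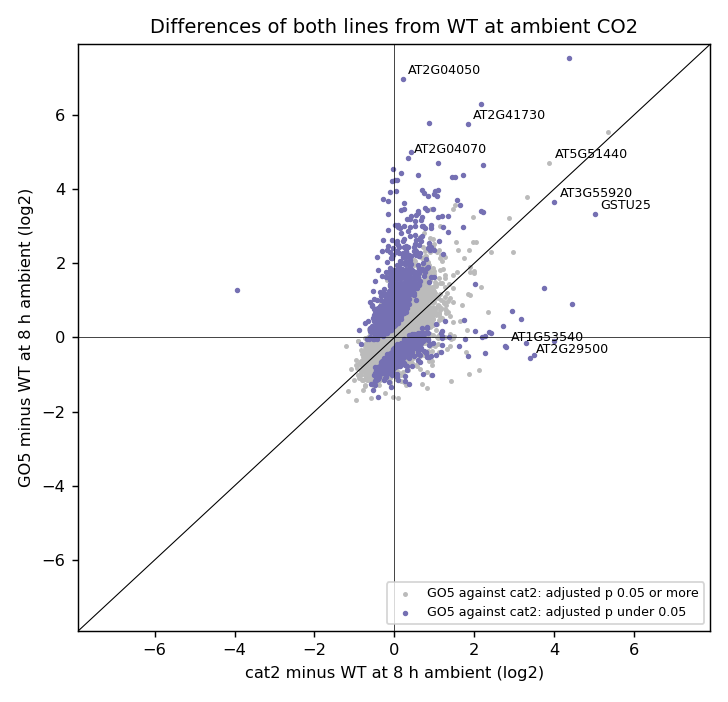
Log2 difference GO5 minus WT against cat2 minus WT at ambient CO2, 1 point per probe set, purple where GO5 and cat2 differed at an adjusted p under 0.05. Purple points number 1865, and r across all points was 0.574.

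The move itself was examined within each genotype, at ambient against high CO2 after 8 h. Here a gene that rose or fell was higher or lower at ambient than at high CO2 at 8 h. Ambient arrays were not compared with 0 h, so a change since the start of the move is not shown. In WT, AT5G47330 rose by 5.56 ± 0.29 (47.2-fold, n = 3, adjusted p = 6.03e-11), ahead of AT1G30250 (5.26 ± 0.40), the AP2/ERF transcription factors AT1G64380 (4.78 ± 0.45) and AT4G28140 (4.68 ± 0.39), AT5G53710 (4.07 ± 0.36), the wax ester synthase WSD1 (3.96 ± 0.39), AT4G39320 (3.90 ± 0.32) and AT2G16630 (3.88 ± 0.24). Lower at ambient CO2 were the cytochrome P450 CYP71B22 (-2.59 ± 0.30), the expansin EXPA8 (-2.53 ± 0.71), AT5G40450 (-2.15 ± 0.52), AT4G21870 (-2.10 ± 0.35), AT3G05900 (-2.02 ± 0.56), the ARGOS-like gene ARL (-1.88 ± 0.44), AT1G66940 (-1.85 ± 0.20) and AT5G57760 (-1.73 ± 0.31). All 5 measured flavonoid and anthocyanin genes rose (5 adjusted over the list alone), including UF3GT (2.33 ± 0.27), DFR, which encodes dihydroflavonol reductase (2.33 ± 0.35), AT4G14090 (1.82 ± 0.35) and UGT78D2 (1.67 ± 0.47). The flavonoid list median was 1.82 log2 (camera adjusted p = 2.38e-09, and adjusted p = 0.0372 with an estimated correlation). In WT at high CO2 the same list was lower at 8 h than at 0 h (median -0.91 log2). A higher value at ambient CO2 may therefore reflect a smaller fall since 0 h, which was not tested. Of 4 abscisic acid, cold and drought genes 2 rose (4 adjusted over the list alone), the dehydrin LTI30 (3.24 ± 0.27) and COR15A (2.40 ± 0.61). The abscisic acid list median was 2.04 log2 (camera adjusted p = 1.13e-05, and adjusted p = 0.105 with an estimated correlation).

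In WT 1085 probe sets passed, 633 higher and 452 lower at ambient CO2 (824 and 316 after median centring, 2164 and 2407 at an unadjusted p under 0.05). Of the 1085, 428 differed by 2-fold or more. Array weights gave 6663 (2896 and 3767, a turned majority), the 6 compared arrays alone 153, and the fit without the 2 arrays that stood apart 694. Leaving out WT ambient replicate 1 or 2 gave 587 and 3247, and WT high replicate 1 or 2 gave 603 and 618. Without WT ambient replicate 2 the majority turned, with 1250 higher and 1997 lower. Of 22 named genes 17 passed whichever array was left out (4 and 1 were lost without WT ambient replicates 1 and 2, and 3, 4 and 3 without WT high replicates 1, 2 and 3).

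In cat2, AT5G47330 (5.82 ± 0.29, 56.6-fold, n = 3, adjusted p = 2.39e-11), AT4G28140 (5.11 ± 0.39), AT1G30250 (4.28 ± 0.40), AT5G53710 (4.14 ± 0.36), AT1G64380 (4.12 ± 0.45) and AT4G39320 (4.06 ± 0.32) rose at ambient CO2, as did GSTU25 (4.83 ± 0.49) and AT2G29500 (3.97 ± 0.54). The expansin EXPA8 (-3.53 ± 0.71), the AUX/IAA gene IAA29 (-2.52 ± 0.67) and the transcription factor BZIP61 (-2.93 ± 0.56) fell. Also lower were AT5G12050 (-3.18 ± 0.77), AT5G66590 (-2.51 ± 0.50), AT5G03120 (-2.498 ± 0.40), AT5G57760 (-2.44 ± 0.31) and AT5G02540 (-2.41 ± 0.71).

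Again all 5 flavonoid genes rose in cat2 (5 adjusted over the list alone), with DFR at 2.33 ± 0.35 and UF3GT at 1.96 ± 0.27. The median flavonoid difference was 1.78 log2 (camera adjusted p = 4.07e-08, and adjusted p = 0.0495 with an estimated correlation). The detoxification list had 4 of 7 higher (5 adjusted over the list alone), with GSTU22 at 1.29 ± 0.25 and UGT73B5 at 1.22 ± 0.35. The median detoxification difference was 1.06 log2 (camera adjusted p = 1.65e-06, and adjusted p = 0.074 with an estimated correlation). Oxidative stress markers rose in 4 of 6 cases (5 adjusted over the list alone), with AT1G10585 at 3.54 ± 0.53 and AT2G21640 at 1.51 ± 0.40. The median marker difference was 1.88 log2 (camera adjusted p = 5.21e-05, and adjusted p = 0.147 with an estimated correlation). Heat shock genes rose in 3 of 7 (3 adjusted over the list alone), with AT5G51440 at 3.47 ± 0.73 and AT1G53540 at 2.86 ± 0.43. The heat shock list median was 1.02 log2 (camera adjusted p = 0.000429, and adjusted p = 0.212 with an estimated correlation). Early-response genes rose in 4 of 5 (4 adjusted over the list alone), with WRKY6 at 2.54 ± 0.50 and CML38 at 1.87 ± 0.58. The early-response list median was 1.87 log2 (camera adjusted p = 0.000476, and adjusted p = 0.27 with an estimated correlation). For abscisic acid, cold and drought 1 of 4 rose (3 adjusted over the list alone), LTI30 at 3.59 ± 0.27. The median abscisic acid difference was 1.44 log2 (camera adjusted p = 2.9e-05, and adjusted p = 0.12 with an estimated correlation). For jasmonate 2 of 3 rose (2 adjusted over the list alone), JMT, a jasmonate methyltransferase, at 1.31 ± 0.33 and OPCL1 at 0.81 ± 0.23. The jasmonate list median was 0.83 log2 (camera adjusted p = 0.0167, and adjusted p = 0.105 with an estimated correlation). For endoplasmic reticulum folding 1 of 4 rose (3 adjusted over the list alone), the transcription factor BZIP60 at 1.03 ± 0.28. The median folding difference was 0.48 log2 (camera adjusted p = 0.0195, and adjusted p = 0.332 with an estimated correlation).

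The cat2 count was 2563, 1174 higher and 1389 lower at ambient CO2 (1233 and 973 after median centring, which turns the majority). By 2-fold or more 879 differed, 620 higher and 259 lower, again a turned majority. Array weights gave 6237 calls and the fit without the 2 arrays that stood apart 4507. Leaving out cat2 ambient replicate 1 or 2 gave 1311 and 1231, and cat2 high replicate 1 or 3 gave 1538 and 1533. The majority turned without cat2 ambient replicate 1 (676 and 635), cat2 ambient replicate 2 (619 and 612) or cat2 high replicate 3 (776 and 757). Of 37 named genes 25 passed whichever array was left out (11 and 12 were lost without cat2 ambient replicates 1 and 2, and 10, 3 and 9 without cat2 high replicates 1, 2 and 3).

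In GO5, AT5G47330 (5.54 ± 0.29, 46.5-fold, n = 3, adjusted p = 1.37e-10), AT4G28140 (4.61 ± 0.39), LTI30 (4.58 ± 0.27), the bHLH gene AT1G10585 (4.51 ± 0.53), AT1G30250 (4.31 ± 0.40), the light-signalling factor HYH (3.95 ± 0.47), AT2G32020 (3.85 ± 0.32) and AT1G64380 (3.81 ± 0.45) rose at ambient CO2. In WT at high CO2, HYH was lower at 8 h than at 0 h, and GO5 was not compared over time. Among the decreases were EXPA8 (-3.06 ± 0.71) and the expansin-like EXLA1 (-2.28 ± 0.21), with BZIP61 (-2.62 ± 0.56), IAA29 (-2.37 ± 0.67), AT5G12050 (-2.71 ± 0.77), AT5G03120 (-2.69 ± 0.40), AT4G19430 (-2.61 ± 0.49) and AT4G21870 (-2.27 ± 0.35).

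Detoxification genes rose in 6 of 7 cases in GO5 (6 adjusted over the list alone), with GSTU25 at 3.10 ± 0.49, AT2G04050 at 3.02 ± 0.58 and UGT73B4 at 2.85 ± 0.30. The detoxification list median was 2.54 log2 (camera adjusted p = 1.73e-08, and adjusted p = 0.0372 with an estimated correlation). Oxidative stress markers rose in 5 of 6 (5 adjusted over the list alone), with AT3G28580 at 3.52 ± 0.40 and AT1G57630 at 2.90 ± 0.74. The marker list median was 2.71 log2 (camera adjusted p = 8.43e-07, and adjusted p = 0.0882 with an estimated correlation). H2O2-scavenging enzymes rose in 3 of 8 (3 adjusted over the list alone): the glutathione reductase GR1 (1.54 ± 0.24), the stromal ascorbate peroxidase SAPX (0.98 ± 0.14) and the monodehydroascorbate reductase ATMDAR2 (0.78 ± 0.20). The scavenging list median was 0.31 log2 (camera adjusted p = 0.0329, and adjusted p = 0.292 with an estimated correlation). All 5 flavonoid genes rose (5 adjusted over the list alone), with DFR at 2.59 ± 0.35. The flavonoid list median was 1.72 log2 (camera adjusted p = 9.14e-07, and adjusted p = 0.074 with an estimated correlation). All 4 abscisic acid, cold and drought genes rose (4 adjusted over the list alone), with COR15A at 2.41 ± 0.61 and COR15B at 1.84 ± 0.61. The abscisic acid list median was 2.12 log2 (camera adjusted p = 3.03e-05, and adjusted p = 0.12 with an estimated correlation). Early-response genes rose in 4 of 5 (4 adjusted over the list alone), with WRKY6 at 2.82 ± 0.50 and CML38 at 2.505 ± 0.58. The median early-response difference was 2.39 log2 (camera adjusted p = 0.00146, and adjusted p = 0.317 with an estimated correlation). Jasmonate genes rose in 2 of 3 (2 adjusted over the list alone), with JMT at 1.34 ± 0.33. The median jasmonate difference was 1.07 log2 (camera adjusted p = 0.0329, and adjusted p = 0.142 with an estimated correlation).

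The GO5 count was 4022, 1750 higher and 2272 lower at ambient CO2. By 2-fold or more 1207 differed, 890 higher and 317 lower, which turns the majority. GAPDH 3'/5' was lower at ambient than at high CO2 in GO5 (difference -0.34 log2, exact permutation p = 0.1, the smallest possible). Leaving out GO5 ambient replicate 2 gave 2309 calls and GO5 high replicate 1 gave 2672. Of 39 named genes 30 passed whichever array was left out (2 and 8 were lost without GO5 ambient replicates 1 and 2, and 2 and 5 without GO5 high replicates 1 and 3). The 3 responses to the move share no arrays: WT and cat2 had 397 higher and 243 lower calls in common with 0 opposite (32.7 and 27.6 by chance). WT and GO5 had 383 and 249 with 6 opposite (48.7 and 45.2 by chance), and cat2 and GO5 had 758 and 860 with 6 opposite (90.3 and 139 by chance).

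The lines were compared with WT at high CO2 and at 0 h, where high CO2 keeps photorespiration low. AT3G55920 was the 1 gene past the threshold in cat2 at high CO2 (4.19 ± 0.09, n = 3, adjusted p = 1.66e-18), and it was also higher in cat2 at 0 h (3.70 ± 0.09), in GO5 at high CO2 (4.14 ± 0.09) and in GO5 at 0 h (3.76 ± 0.09). AT2G04050 was higher in GO5 at high CO2 by 3.94 ± 0.58 (adjusted p = 0.00682), with an SD of 2.196 among the GO5 arrays. A probe set that is not paired with a gene here was lower in cat2 at high CO2 (-3.06 ± 0.43), at 0 h (-4.68 ± 0.43) and at ambient CO2 (-3.94 ± 0.43). A probe set without a single gene name was higher in GO5 at high CO2 (1.81 ± 0.12), at 0 h (0.90 ± 0.12) and at ambient CO2 (1.80 ± 0.12). Both were chosen after their values were seen, and what they measure remains to be looked up in the array annotation.

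No list member passed in these comparisons apart from AT2G04050, by limma over all probe sets. In cat2 at high CO2 the early-response genes ranked below other genes with 0 of 5 past the threshold (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The early-response list median was -0.89 log2 (camera adjusted p = 0.00138, and adjusted p = 0.317 with an estimated correlation). The oxidative stress markers ranked below other genes there as well, with 0 of 6 past it (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median marker difference was -0.50 log2 (camera adjusted p = 0.0029, and adjusted p = 0.316 with an estimated correlation). In GO5 at high CO2 the detoxification list ranked above other genes with 1 of 7 past the threshold (1 adjusted over the list alone). The median detoxification difference was 0.30 log2 (camera adjusted p = 0.00152, and adjusted p = 0.212 with an estimated correlation). At 0 h the flavonoid genes ranked below other genes in cat2, with 0 of 5 past the threshold (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median flavonoid difference was -0.22 log2 (camera adjusted p = 0.0117, and adjusted p = 0.353 with an estimated correlation). Flavonoid genes ranked below other genes in GO5 at 0 h as well, with 0 of 5 past it (0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The flavonoid list median was -0.28 log2 (camera adjusted p = 0.0236, and adjusted p = 0.433 with an estimated correlation). The heat shock list ranked below other genes in GO5 at 0 h (0 of 7, 0 at an unadjusted p under 0.05, 0 adjusted over the list alone). The median heat shock difference was -0.27 log2 (camera adjusted p = 0.013, and adjusted p = 0.395 with an estimated correlation).

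At high CO2 2 probe sets passed in cat2 (1 higher and 1 lower, 918 at an unadjusted p under 0.05) and 3 in GO5 (3 higher and 0 lower, 572 at an unadjusted p under 0.05, of which 239 lower). At 0 h 2 passed in cat2 (1 higher and 1 lower, 224 unadjusted) and 2 in GO5 (2 higher and 0 lower, 300 unadjusted, of which 122 lower). GAPDH 3'/5' was lower in cat2 than in WT at high CO2 (difference -0.33 log2, exact permutation p = 0.1, the smallest possible). The high CO2 counts were 1 in cat2 with the 6 compared arrays alone and 33 in GO5 with array weights, and at 0 h the GO5 count was 1 with the 6 compared arrays alone. For cat2 the count was 12 without WT high replicate 3 and 1 and 4 without cat2 high replicate 2 or 3, and for GO5 it was 7 without WT high replicate 3 (3 higher and 4 lower) and 16 without GO5 high replicate 2, while AT2G04050 did not pass without WT high replicate 2 or GO5 high replicate 1.

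**Figure D4:**
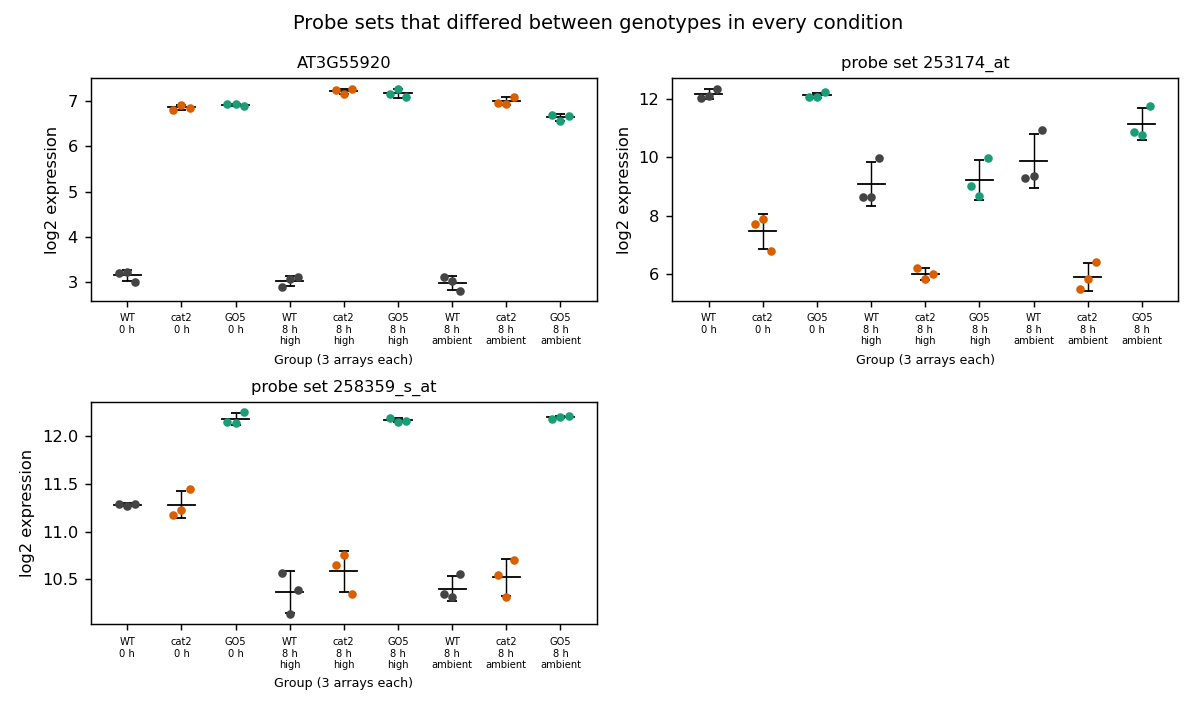
Log2 signal per array (points) in 9 groups for AT3G55920 and 2 probe sets that have no single gene name here. Every WT array of AT3G55920 lies at or below 3.24 and every array of both lines at or above 6.55.

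WT at 8 h of high CO2 was compared with WT at 0 h, which differ in hours of light and age and not in CO2. The J-domain gene AT1G56300 rose by 6.41 ± 0.16 (84.8-fold, n = 3, adjusted p = 3.26e-17), with AT4G16146 (5.36 ± 0.33), the pectin methylesterase inhibitor-like AT5G62360 (5.30 ± 0.32), the CCT-motif gene AT1G07050 (5.12 ± 0.68), AT3G62550 (4.91 ± 0.26), AT4G30650 (4.51 ± 0.32) and the cold-regulated COR15B (5.02 ± 0.61) and COR27 (4.56 ± 1.06). Lower at 8 h were the cysteine protease gene AT2G27420 (-5.09 ± 0.64), AT3G15310 (-4.62 ± 0.57), AT2G15020 (-4.20 ± 0.77), HYH (-4.09 ± 0.47), the adenosylmethionine decarboxylase gene AT5G15950 (-3.92 ± 0.23), AT5G42760 (-3.91 ± 0.55), the glutaredoxin-like AT1G64500 (-3.91 ± 0.68) and AT1G55960 (-3.86 ± 0.51).

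All 4 abscisic acid, cold and drought genes rose by 8 h (4 adjusted over the list alone), among them COR15A (2.91 ± 0.61), LTI30 (2.08 ± 0.27) and COR47 (1.24 ± 0.31). The median abscisic acid difference was 2.498 log2 (camera adjusted p = 7.21e-06, and adjusted p = 0.105 with an estimated correlation). All 3 Calvin-Benson genes fell (3 adjusted over the list alone): SBPASE (-0.89 ± 0.17), PRK (-0.51 ± 0.15) and the Rubisco activase RCA (-0.41 ± 0.13). The Calvin-Benson list median was -0.51 log2 (camera adjusted p = 0.00547, and adjusted p = 0.27 with an estimated correlation). Photorespiration genes fell in 4 of 8 cases (5 lower and 1 higher adjusted over the list alone), namely the hydroxypyruvate reductase HPR (-0.82 ± 0.18), LrgB (-0.74 ± 0.14), AT1G80380 (-0.62 ± 0.10) and the aminomethyltransferase AT1G11860 (-0.61 ± 0.15). The median photorespiration difference was -0.47 log2 (camera adjusted p = 0.00946, and adjusted p = 0.332 with an estimated correlation). Flavonoid genes fell in 2 of 5 (4 adjusted over the list alone), UGT78D2 (-2.11 ± 0.47) and DFR (-2.03 ± 0.35). The median flavonoid difference was -0.91 log2 (camera adjusted p = 0.00146, and adjusted p = 0.252 with an estimated correlation).

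The count was 3042, 1564 higher and 1478 lower at 8 h (1187 and 1858 after median centring, which turns the majority), 1120 by 2-fold or more (544 higher and 576 lower). GAPDH 3'/5' was higher at 8 h by 0.56 log2 (exact permutation p = 0.1, the smallest possible), and with it as a covariate the count was 1793, against 5048 with array weights. This majority also turned after quantile normalization (1479 and 1548), without WT 0 h replicate 2 (1349 and 1354) and without WT high replicate 3 (1385 and 1394). Of 28 named genes 25 passed whichever array was left out (2, 2 and 2 were lost without WT 0 h replicates 1, 2 and 3, and 2, 3 and 1 without WT high replicates 1, 2 and 3).

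Whether the move changed transcripts more in a line than in WT was tested as a difference of responses, ambient minus high CO2. In cat2 minus WT, GSTU25 differed most (4.72 ± 0.69, n = 3 arrays in each of 4 groups, adjusted p = 0.00346), with the subtilase SBT3.5 (2.53 ± 0.44), AT5G16980 (2.08 ± 0.34), the cinnamyl alcohol dehydrogenase-like AT1G09500 (1.90 ± 0.24), AT4G15420 (1.27 ± 0.23) and the ubiquitin-conjugating enzyme gene UBC30 (0.62 ± 0.12). The detoxification list had 1 of 7 members with a larger response in cat2 (4 adjusted over the list alone). The detoxification list median was 1.00 log2 (camera adjusted p = 4.24e-06, and adjusted p = 0.074 with an estimated correlation). For heat shock genes the response ranked higher in cat2 than for other genes, with 0 of 7 past the limma threshold (4 at an unadjusted p under 0.05, 4 adjusted over the list alone). The heat shock list median was 2.59 log2 (camera adjusted p = 0.000115, and adjusted p = 0.152 with an estimated correlation). The oxidative stress markers also ranked higher with 0 of 6 past it (4 at an unadjusted p under 0.05, 1 adjusted over the list alone). The marker list median was 1.67 log2 (camera adjusted p = 1.95e-05, and adjusted p = 0.127 with an estimated correlation). Early-response genes ranked higher in cat2 with 0 of 5 past it (1 unadjusted, 0 adjusted over the list alone). The median early-response difference was 1.18 log2 (camera adjusted p = 0.00819, and adjusted p = 0.433 with an estimated correlation). Endoplasmic reticulum folding genes ranked higher in cat2 with 0 of 4 past it (0 unadjusted, 0 adjusted over the list alone). The folding list median was 0.55 log2 (camera adjusted p = 0.00771, and adjusted p = 0.27 with an estimated correlation).

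The cat2 minus WT count was 22, 21 with a higher and 1 with a lower response in cat2 (976 and 1549 at an unadjusted p under 0.05, a turned majority). It was 4041 with array weights (1729 and 2312, a turned majority), 239 without the 2 arrays that stood apart, 1 with the 12 compared arrays alone and 9 with dim probe sets left out. Leaving out 1 array gave 10 and 49 without WT ambient replicates 2 and 3, 13, 12 and 41 without WT high replicates 1, 2 and 3, 13, 7 and 218 without cat2 ambient replicates 1, 2 and 3, and 13 and 11 without cat2 high replicates 1 and 3. Of the 6 named genes 2 passed whichever array was left out (1 and 3 lost without WT ambient replicates 1 and 2, 2 and 3 without WT high replicates 1 and 2, 3 and 4 without cat2 ambient replicates 1 and 2, 3, 2 and 3 without cat2 high replicates 1, 2 and 3).

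In GO5 minus WT, AT3G28580 (3.99 ± 0.57, n = 3 arrays in each of 4 groups, adjusted p = 0.00053), AT2G41730 (3.87 ± 0.68), AT2G04070 (3.83 ± 0.49), SUFE2, an activator of sulfur transfer in plastids (3.82 ± 0.78), AT2G32020 (3.66 ± 0.45), the receptor-like kinase AT1G74360 (3.36 ± 0.66), AT1G26380 (3.32 ± 0.89) and AT2G23270 (3.32 ± 0.39) responded more in GO5. AT5G50915 (-1.86 ± 0.36), the GDSL lipases AT4G28780 (-1.71 ± 0.43) and AT5G45960 (-1.56 ± 0.37), the brassinosteroid-responsive EXO (-1.61 ± 0.35), EXLA1 (-1.598 ± 0.30), AT1G75960 (-1.48 ± 0.32), AT4G37240 (-1.26 ± 0.33) and AT1G36390 (-1.26 ± 0.18) had lower responses. The detoxification list had 4 of 7 higher (5 adjusted over the list alone), with UGT73B4 at 2.96 ± 0.42, AT2G04050 at 3.02 ± 0.82 and GSTU25 at 2.98 ± 0.69. The median detoxification difference was 2.61 log2 (camera adjusted p = 5.14e-08, and adjusted p = 0.0417 with an estimated correlation). Oxidative stress markers were higher in 2 of 6 (6 adjusted over the list alone), AT1G10585 at 3.27 ± 0.75. The median marker difference was 2.46 log2 (camera adjusted p = 3.48e-07, and adjusted p = 0.0773 with an estimated correlation). Early-response genes ranked above other genes with 0 of 5 past the limma threshold (2 unadjusted, 1 adjusted over the list alone). The early-response list median was 1.63 log2 (camera adjusted p = 0.014, and adjusted p = 0.463 with an estimated correlation). Photorespiration had 1 of 8 lower (2 adjusted over the list alone), AT1G80380 at -0.57 ± 0.14. The photorespiration list median was -0.38 log2 (camera adjusted p = 0.026, and adjusted p = 0.434 with an estimated correlation), and -0.48 after median centring.

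Over all probe sets the median GO5 minus WT difference was -0.05, and -0.15 after median centring, a shift of -0.10. Of the 22 cat2 minus WT and 633 GO5 minus WT calls, 8 higher and 1 lower were shared (0.304 and 0.0134 by independent lists). Across probe sets r was 0.673. Draws with no effects, which shared a reference of random arrays, gave a median r of 0.567 (-0.493 to 0.929). The covariance was 0.139, inside the range of these draws (median 0.0509, highest 0.182). The count was 633, 329 higher and 304 lower in GO5 (290 and 525 after median centring), 3802 with array weights, 13 with the 12 compared arrays alone, 1248 with the GAPDH covariate and 1030 with replicate number as a block. The majority turned under median centring, quantile normalization (346 and 401), dim probe sets left out (257 and 343), the block (499 and 531), the GAPDH covariate (599 and 649) and array weights (1734 and 2068). It also turned without WT ambient replicate 3 (359 and 387) or WT high replicate 3 (454 and 473), and at an unadjusted p under 0.05 (1745 and 2318). Leaving out 1 array gave 1675 without WT ambient replicate 2, 204 and 320 without WT high replicates 1 and 2, 1162 and 190 without GO5 ambient replicates 1 and 2, and 230 and 303 without GO5 high replicates 1 and 2. Of the 22 named genes 13 passed whichever array was left out (5, 1 and 3 lost without WT ambient replicates 1, 2 and 3, 8, 7 and 2 without WT high replicates 1, 2 and 3, 1, 9 and 2 without GO5 ambient replicates 1, 2 and 3, 9, 8 and 3 without GO5 high replicates 1, 2 and 3).

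In GO5 minus cat2, AT2G32020 (3.65 ± 0.45, n = 3 arrays in each of 4 groups, adjusted p = 0.000222), AT2G23270 (3.21 ± 0.39), AT2G20720 (3.15 ± 0.50), AT4G37290 (2.87 ± 0.50), AT2G04070 (2.86 ± 0.49), AT1G71530 (2.72 ± 0.41), NDB4 (2.68 ± 0.51) and AT3G28580 (2.62 ± 0.57) responded more in GO5. The small heat shock proteins AT2G29500 (-3.94 ± 0.76) and AT1G53540 (-2.96 ± 0.60) responded less in GO5, as did AT5G16980 (-1.84 ± 0.34), AT5G50915 (-1.72 ± 0.36), AT5G05220 (-1.24 ± 0.28), AT1G29310 (-0.99 ± 0.21), AT2G32520 (-0.98 ± 0.20) and the proteasome subunit gene AT1G79210 (-0.93 ± 0.19). Heat shock genes were lower in 2 of 7 (3 adjusted over the list alone). The median heat shock difference was -1.24 log2 (camera adjusted p = 7.55e-05, and adjusted p = 0.147 with an estimated correlation). Oxidative stress markers were higher in 1 of 6 (1 adjusted over the list alone). The marker list median was 0.63 log2 (camera adjusted p = 0.026, and adjusted p = 0.465 with an estimated correlation).

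The count was 112, 71 higher and 41 lower in GO5 (52 and 49 after median centring), 479 with array weights, 279 without the 2 arrays that stood apart (113 higher and 166 lower, which turns the majority), 6 with the 12 compared arrays alone and 44 with dim probe sets left out. Without cat2 ambient replicate 3 the majority turned as well (61 and 78). Leaving out 1 array gave 70 without cat2 ambient replicate 1, 63, 63 and 66 without cat2 high replicates 1, 2 and 3, 367, 61 and 72 without GO5 ambient replicates 1, 2 and 3, and 66 and 57 without GO5 high replicates 1 and 2. Of the 16 named genes 8 passed whichever array was left out (4, 6 and 2 lost without cat2 ambient replicates 1, 2 and 3, 7, 7 and 4 without cat2 high replicates 1, 2 and 3, 7 and 6 without GO5 ambient replicates 2 and 3, 6, 7 and 4 without GO5 high replicates 1, 2 and 3).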

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

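The tests on AT3G55920 and the test of spread among the cat2 arrays were chosen only after the result was seen, and all 3 weighed patterns were picked from the data. The differences of transfer responses are given here because the tested difference between genotypes passed its threshold.

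In cat2 minus WT, 22 probe sets passed, and the list medians, each given with its adjusted p with an estimated correlation, were 2.59 for heat shock (adjusted p = 0.152), 1.67 for oxidative stress markers (adjusted p = 0.127), 1.00 for detoxification (adjusted p = 0.074), 1.18 for early response (adjusted p = 0.433) and 0.55 for endoplasmic reticulum folding (adjusted p = 0.27). The named genes were GSTU25 at 4.72 ± 0.69, SBT3.5 at 2.53 ± 0.44, AT5G16980 at 2.08 ± 0.34, AT1G09500 at 1.90 ± 0.24, AT4G15420 at 1.27 ± 0.23 and UBC30 at 0.62 ± 0.12.

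In GO5 minus WT, 633 probe sets passed, and the list medians, each given with its adjusted p with an estimated correlation, were 2.61 for detoxification (adjusted p = 0.0417), 2.46 for oxidative stress markers (adjusted p = 0.0773), 1.63 for early response (adjusted p = 0.463) and -0.38 for photorespiration (adjusted p = 0.434). Higher responses in GO5 were those of AT3G28580 (3.99 ± 0.57), AT2G41730 (3.87 ± 0.68), AT2G04070 (3.83 ± 0.49), SUFE2 (3.82 ± 0.78), AT2G32020 (3.66 ± 0.45), AT1G74360 (3.36 ± 0.66), AT1G26380 (3.32 ± 0.89) and AT2G23270 (3.32 ± 0.39). Lower ones were those of AT5G50915 (-1.86 ± 0.36), AT4G28780 (-1.71 ± 0.43), EXO (-1.61 ± 0.35), EXLA1 (-1.598 ± 0.30), AT5G45960 (-1.56 ± 0.37), AT1G75960 (-1.48 ± 0.32), AT4G37240 (-1.26 ± 0.33) and AT1G36390 (-1.26 ± 0.18).

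In GO5 minus cat2, 112 probe sets passed, and the list medians, each given with its adjusted p with an estimated correlation, were -1.24 for heat shock (adjusted p = 0.147) and 0.63 for oxidative stress markers (adjusted p = 0.465). Higher in GO5 were AT2G32020 (3.65 ± 0.45), AT2G23270 (3.21 ± 0.39), AT2G20720 (3.15 ± 0.50), AT4G37290 (2.87 ± 0.50), AT2G04070 (2.86 ± 0.49), AT1G71530 (2.72 ± 0.41), NDB4 (2.68 ± 0.51) and AT3G28580 (2.62 ± 0.57). Lower were AT2G29500 (-3.94 ± 0.76), AT1G53540 (-2.96 ± 0.60), AT5G16980 (-1.84 ± 0.34), AT5G50915 (-1.72 ± 0.36), AT5G05220 (-1.24 ± 0.28), AT1G29310 (-0.99 ± 0.21), AT2G32520 (-0.98 ± 0.20) and AT1G79210 (-0.93 ± 0.19).

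Counts from other splits of the same arrays bear on these differences of responses. For cat2 minus WT 6 of 100 splits gave at least the real 22 calls (highest other 2328), for GO5 minus WT 8 gave at least 633 (highest other 1974) and for GO5 minus cat2 9 gave at least 112 (highest other 1138). Of the splits that keep the real ambient labels, 4 of 8, 8 of 10 and 9 of 10 gave as many, which are 4 of those 6 and all of those 8 and 9. Such splits still hold the ambient difference between genotypes, so these counts do not decide whether chance is excluded. For GO5 minus WT and GO5 minus cat2 every split that reached the real count keeps these labels, so the high counts do not point to other structure. For cat2 minus WT not all of the 6 keep them, which may point to structure among the samples. Its source was not tested.

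For the comparisons of 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 160 and 750 for cat2 against WT at ambient CO2, where 3 of the 10 gave as many, the real one included, which also points to structure among the samples. They were 4193 and 170 for GO5 against WT (1 of 10), 1865 and 24 for GO5 against cat2 (1 of 10), 1085 and 25 for the WT transfer (1 of 10), 2563 and 0 for cat2 (1 of 10) and 4022 and 2 for GO5 (1 of 10). At high CO2 they were 2 and 4 in cat2 (2 of 10) and 3 and 14 in GO5 (2 of 10), at 0 h 2 and 0 in each line (1 of 10), and for WT at 8 h against 0 h 3042 and 0 (1 of 10).

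AT3G55920 had a mean of 3.06 in the 9 WT arrays and 6.97 in the 18 arrays of both lines. The lowest line array lies 3.32 log2 above the highest WT array, which argues against a swap of a WT array with a line array. The gene was named because its groups did not overlap, so the gap is not independent of that choice. Both lines lie high, so the gap cannot show a swap between cat2 and GO5 or between conditions. The difference from WT changed by -0.49 in 1 line and -0.19 in the other between high and ambient CO2, which argues against a response to H2O2 formed after the move. A difference between seed stocks may underlie it. Among the 6 nearest measured neighbours the largest absolute difference was 0.714 (AT3G55890 at -0.71 ± 0.12, opposite in direction). The means of AT3G55890, 3.37 in WT and 2.65 in the lines, lie near the background, as does the WT mean of AT3G55920. Signals this low limit what a neighbour can show, so the values leave a shift of the neighbouring region open. A genotype effect common to both lines stays open as well and was not tested.

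Fewer probe sets differed from WT in cat2 (160) than in GO5 (4193) at ambient CO2, a gap that depended on the WT arrays: the counts were 1072 and 5189 without WT ambient replicate 2, and 6532 and 6764 with array weights, which rest largely on 1 WT array. With cat2 ambient replicate 3 left out, the highest cat2 count was 639, or 0.152 of the GO5 count, which argues against 1 cat2 array that stands apart as the whole cause. The cat2 to GO5 ratio of median SDs was 0.929 (0.588 to 1.35 with 1 array left out), a range that does not decide whether the cat2 arrays spread more. The pooled variance with 3 arrays per group gives both comparisons the same SE (median 0.151) by construction. A larger cat2 spread could therefore not lower the cat2 count alone through the SE, whatever that spread was. The equal SE is no test of the spread itself. A larger transcript response in GO5 may account for the difference: the effects had an SD of 0.449 in GO5 and 0.216 in cat2 after removal of the sampling variance, a ratio of 2.08 that ran from 1.47 to 2.80 with 1 array left out. The lower end of that range lies under the 1.5 set for this test, which keeps it open.

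Many calls between GO5 and WT at ambient CO2 stood beside a higher GAPDH 3'/5' difference in the WT arrays. With that difference as a covariate the called probe sets kept a median share of 1.13 of their log2 difference (1.02 to 1.24 with 1 array left out), which argues against RNA quality as measured by GAPDH as the whole cause. Without WT ambient replicate 2, the array with the highest value, the count was 5189, or 1.24 times the count with it. A difference in the transcripts of the line may account for the count, a hypothesis taken from the same arrays that was not tested. The count depended on the pooled variance, with 206 calls from the 6 compared arrays alone. Of the 4193 calls 3228 passed with the GAPDH covariate.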

How the results depend on the processing

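The fit without the 2 arrays that stood apart (WT ambient replicate 1 and cat2 ambient replicate 3) and the fit with the GAPDH 3'/5' covariate were chosen only after seeing the data. Each of 244 gene results was refitted under the alternatives, 3848 comparisons in all. In 3375 the gene kept its direction and its side of the threshold, in 473 it kept the direction and did not pass, and in 0 the direction turned. For 120 of the 244 results every refit kept the direction and the side of the threshold. Genes named by size in a pairwise comparison had groups that did not overlap. Leaving out 1 array could not turn their direction, so the 0 tests little. With only the arrays of the groups compared 108 of the gene results did not pass, where the variance rests on fewer arrays. Quantile normalization, median centring and variances with trend and robust settings moved no total of calls by more than 1.5 times. By direction, the lower calls went from 43 to 23 (centring) and 22 (trend and robust) in cat2 against WT at ambient CO2, from 2240 to 3412 (centring) in GO5 against WT and from 304 to 525 (centring) in GO5 minus WT, and the 1 lower call of cat2 minus WT was lost with quantile normalization and with trend and robust settings.

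Array weights gave 6532 calls for cat2 against WT at ambient CO2, 6764 for GO5 against WT, 6663 and 6237 for the WT and cat2 transfers, 33 for GO5 against WT at high CO2, 5048 for WT at 8 h against 0 h, and 4041, 3802 and 479 for cat2 minus WT, GO5 minus WT and GO5 minus cat2. The weights did not converge, and 1 WT ambient array took a weight of 19.6. Only the compared arrays gave 7, 206 and 64 for cat2 against WT, GO5 against WT and GO5 against cat2 at ambient CO2, 153 for the WT transfer, 1 for cat2 at high CO2, 1 for GO5 at 0 h, and 1, 13 and 6 for the 3 differences of responses in the same order. Without the arrays that stood apart the counts were 433 for cat2 at ambient CO2, 694 and 4507 for the WT and cat2 transfers, 239 for cat2 minus WT and 279 for GO5 minus cat2 (113 higher and 166 lower, a turned majority). The GAPDH covariate gave 1793 for WT at 8 h against 0 h and 1248 for GO5 minus WT. A similar total can hold other probe sets. With this covariate cat2 against WT at ambient CO2 had 146 calls, 87 of them among the 160 without it. GO5 against WT had 4484, with 3228 among the 4193 without it. Dim probe sets left out gave 9 for cat2 minus WT and 44 for GO5 minus cat2, with fewer probe sets tested. Replicate number as a block gave 1030 for GO5 minus WT, moved no other total by more than 1.5 times (lower calls of cat2 against WT at ambient CO2 went from 43 to 77) and left the 244 gene results and 50 list calls on their side of the threshold. The replicate numbers were not taken as pairs in the tests (only the rule for naming genes in differences of responses used them), although 18 of 27 arrays correlated best with their own number: only in 1 of 11 comparisons, GO5 against cat2 at ambient CO2, did all 3 numbers have correlated deviations above 0.1. The correlations ran from -0.325 to 0.797. In replicate 3 they were positive in all 11 comparisons (0.123 to 0.797), so its arrays shared deviations that the fit without the block did not model. Apart from the settings named with their construction, the cause was not tested.

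With 1 array left out the counts ran from 61 to 1072 for cat2 against WT at ambient CO2, 1926 to 5189 for GO5 against WT, 569 to 2489 for GO5 against cat2, 587 to 3247, 1231 to 3478 and 2309 to 3846 for the WT, cat2 and GO5 transfers, 1 to 12 and 2 to 16 for cat2 and GO5 at high CO2, 2 to 3 and 2 to 3 at 0 h, 2114 to 2779 for WT at 8 h against 0 h, and 7 to 218, 190 to 1675 and 57 to 367 for the 3 differences of responses. Of 50 list calls 6 passed with an estimated correlation, and all 50 passed with the replicate block. The mean of a gene's probe sets left nearly every value as it was (13436 probe sets for 13356 genes) and so tests little. With 3 arrays per group, and signals near the background for many probe sets, the number of arrays limits which of the smaller differences can pass.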

Other observations

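All values in this part were chosen after seeing the data, from a scan of 26 gene families in 14 contrasts (364 tests). With the preset correlation 28 tests passed and with an estimated correlation 0 did, each called family then at an adjusted p = 0.995.

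Signals of plastid-encoded genes fell in GO5 against WT at ambient CO2 in 24 of 69 cases and rose in 0 (median -0.27, -0.28 after quantile normalization, -0.37 after median centring, adjusted p = 0.000425, and adjusted p = 0.995 with an estimated correlation). The decreases included psaC of photosystem I (-1.29 ± 0.28), the ribosomal protein gene rps18 (-0.94 ± 0.18), ndhG of the NDH complex (-0.89 ± 0.14) and ccsA (-0.51 ± 0.08). In the GO5 transfer response 9 of them fell (adjusted p = 0.00219), and in WT at 8 h against 0 h, with no move to ambient CO2, 8 fell (adjusted p = 0.00219). They also ranked below other genes in cat2 against WT at ambient CO2 (2 fell, adjusted p = 0.0193) and at 0 h (0 fell, adjusted p = 0.0118), and in GO5 against cat2 at ambient CO2 (1 rose and 1 fell, adjusted p = 0.0467). The same held for the transfer responses of GO5 minus WT (4 fell, adjusted p = 0.000425) and GO5 minus cat2 (0 fell, adjusted p = 0.00219). With an estimated correlation each of these had an adjusted p = 0.995. In GO5 against WT at ambient CO2, 2240 of all 22746 probe sets were lower at the threshold, and GAPDH 3'/5' differed by -0.63 log2. Whether RNA quality or the 3' IVT labelling bears on the plastid signals was not tested, so they are not read as levels of plastid transcripts.

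Glycosyltransferases of the UGT family rose in 13 of 47 cases and fell in 1 in the GO5 transfer response (median 0.28, adjusted p = 9.47e-06, and adjusted p = 0.995 with an estimated correlation), with UGT73C1 at 3.56 ± 0.35, UGT73B4 at 2.85 ± 0.30 and UGT84A3 at 2.602 ± 0.35. In the cat2 transfer response 9 rose and 1 fell (adjusted p = 0.000425), among them UGT76E12 at 2.73 ± 0.48 and UGT87A2 at 2.14 ± 0.37, and in the WT transfer response 5 rose and 0 fell (adjusted p = 0.0496). The family also passed in GO5 against WT at ambient CO2 (9 rose and 2 fell, adjusted p = 0.0227, median 0.01, -0.09 after median centring) and in GO5 minus WT (3 rose and 0 fell, adjusted p = 0.0201). With an estimated correlation each of these UGT tests had an adjusted p = 0.995. From 0 h to 8 h in WT at high CO2, 3 of 9 XTH genes of cell wall remodelling fell (adjusted p = 0.00783, and adjusted p = 0.995 with an estimated correlation): XTH19 (-3.13 ± 0.34), XTH33 (-1.52 ± 0.21) and XTH32 (-1.50 ± 0.28). In the same comparison 3 of 8 OTP genes of organelle RNA editing rose (adjusted p = 0.0467, and adjusted p = 0.995 with an estimated correlation), with OTP84 at 1.32 ± 0.18. Apart from UGT in GO5 against WT at ambient CO2, the sign of the median was the same after quantile normalization and after median centring in each of these comparisons.

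Among probe sets that name a single gene, the largest pooled SD among replicates over all groups belonged to AT4G12490 (2.21, values from 4.94 to 11.32), followed by AT4G12500 (1.88) and AT3G46280 (1.83), and PDF1.2, a plant defensin gene, stood at 1.66.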
